A study of Mus musculus with 6 samples.

How the data were processed

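Poly(A)-selected RNA was sequenced from 6 mouse cell samples that the labels place in 5 groups. Quiescent satellite cells (QSC), the resident stem cells of skeletal muscle, had 2 libraries, from mouse 1 and mouse 3. Activated satellite cells (ASC), whose title marks them as Pax7-plus and p1, had 1 library. Induced myogenic progenitor cells (iMPCs), made from fibroblasts by reprogramming, were sorted on a nuclear green fluorescent reporter of Pax7, and the reporter-positive and reporter-negative fractions had 1 library each; the labels name embryonic and tail-tip fibroblasts as starting cells but not which of them gave these cultures. Mouse embryonic fibroblasts (MEFs) had 1 library. The QSC libraries are separate mice per the labels, so the p-values given here rest on the spread between these 2 animals. The pair differed in Xist (0.0954 and 530.1 CPM) and the Y-linked Ddx3y (455 and 0.226 CPM), as a male and a female mouse do, so this spread, and every SE and p-value, includes any difference between the sexes.

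Per the labels' protocols, RNA was column-purified with DNase treatment, mRNA was selected on its poly(A) tail and libraries were made with a directional (strand-marking) kit. Per the same protocols, expanded iMPC cultures were kept without doxycycline in a medium with forskolin at 5 µM, which raises cAMP, RepSox at 5 µM, an inhibitor of the TGF-beta type I receptor, and a GSK3 inhibitor at 3 µM, which activates Wnt signalling. The labels give 1 protocol text for all samples and do not say in which medium the ASC and MEF libraries were grown.

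The authors deposited raw read counts per Ensembl gene for each library, with 38924 genes and no normalization. Per the submitters' processing notes, STAR 2.3.0, HTSeq 0.6.0, Picard 1.100 and edgeR were used with the mm9 build; their order, the annotation and whether counting used the strand are not given in the sources used here. Overlapping and antisense genes, and genes with a near-identical copy such as Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or Prl2c2 and Prl2c3, are therefore uncertain as single genes. The authors also deposited a table of RPKM values that pairs gene identifiers with symbols. Dividing the counts by the RPKM values and by the summed counts of each library gave 1 implied gene length per gene in all 6 libraries, with a largest relative deviation of 5.55e-15, so the RPKM values are counts scaled to the summed counts of the library and per kilobase, with no other scaling. All RPKM columns belonged to a labelled library. Symbols came from this table; 204 symbols occurred more than once, and genes were followed by identifier. No coordinates are printed, because the reference genome at hand was of another build.

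Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Libraries were scaled by TMM (trimmed mean of M values) after edgeR's default expression filter by group, which kept 17116 genes. A model with 1 coefficient per group was fitted to all 6 libraries, so that the 4 comparisons with QSC shared 1 scaling and 1 estimate of spread, and each contrast was tested with edgeR's two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment at a threshold of 0.05. Only QSC had more than 1 library, which left 1 residual degree of freedom (prior degrees of freedom 16.3, common dispersion 0.227, biological coefficient of variation 0.476). Every lone library was thus assumed to vary as much as the pair of QSC mice. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The 4 comparisons share the QSC libraries, so no overlap or correlation between them is given.

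For groups of 1 library against each other no p-value was computed. Genes were counted by a fixed rule of size, at least 4-fold on TMM-scaled log2 CPM (counts scaled to library size, prior count 2) with at least 5 CPM in the higher group. Ratios carry exact 95% counting intervals, which like all intervals here cover counting error only: they compare libraries, not conditions. Where a gene had 0 counts in a group, the fold is a lower bound against 3 counts summed over that group, or over the 1 library where it is given by mouse.

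Fixed in advance were the groups, the tests, the rule of size, 23 gene lists with 419 entries, of which 417 matched a gene, and the rule for named genes. Members of a list had to reach 1 CPM in at least 1 library. The lists were satellite cell identity, satellite cell quiescence, myogenic commitment, sarcomere and terminal differentiation, proliferation, fibroblast and extracellular matrix, Hox clusters, Notch pathway, TGF-beta response, Wnt response, cAMP response, immediate early and dissociation stress, imprinted and fetal growth, glycolysis, pluripotency, and markers of endothelial, immune, pericyte and smooth muscle, Schwann and neural crest, adipocyte, cartilage and bone, erythroid and epithelial cells. Each list is described by its members called over all genes, its members called when adjusted over the list alone, its median log2 difference and the percentile of that median among 10000 random lists of the same size matched on mean expression. Genes named were Pax7, Myf5, Myod1, Myog, Mki67 and Col1a1 in every comparison; the 8 genes with the largest difference in each direction (5 in the other comparisons) at 10 CPM or more, without predicted, RIKEN, small RNA, ribosomal protein and pseudogene symbols; up to 3 members per list with the largest difference at 5 CPM or more; and up to 2 markers per marker list at the highest CPM. Not every gene the rule reaches is printed.

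Summed counts were 29279686 and 29001640 in QSC of mouse 1 and mouse 3, 20859611 in ASC, 26351821 in Pax7-positive iMPCs, 24446555 in Pax7-negative iMPCs and 23273130 in MEFs. TMM factors were 0.717 and 0.763 in QSC against 1.11 in ASC, 1.18 and 1.21 in the Pax7-positive and Pax7-negative iMPCs, and 1.15 in MEFs. The QSC mice were distinct libraries: of 14536 genes with 20 or more reads over the pair, 10858 (74.7%) differed beyond sampling noise by an exact binomial test with Benjamini-Hochberg adjustment.

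The steps were tested on simulated counts over 17116 genes, with 50 genes changed at each fold size. Each gene had its mean over all 6 libraries, with the real library sizes and the fitted spread trend in every library. Changed genes were few and balanced in direction. The simulation therefore cannot test whether lone libraries vary like the QSC pair, or the scaling where many genes change. For Pax7-positive iMPCs against QSC, edgeR called 0 of 50 genes changed 2-fold, 8 of 50 changed 4-fold, 27 of 50 changed 8-fold and 37 of 50 changed 16-fold in the right direction, and 5 of 16916 unchanged genes; 178 unchanged genes passed the rule of size. For Pax7-negative iMPCs the calls were 0, 7, 24 and 42, with 6 unchanged genes called and 191 past the rule of size. For ASC they were 1, 10, 26 and 47, with 4 and 176, and for MEFs 0, 5, 26 and 38, with 2 and 172. Of 50 simulated unchanged lists of 20 genes per comparison, 4, 3, 5 and 3 fell outside the central 95% of random lists in the same order, and all 50 lists raised 8-fold lay above it in each.

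Other settings tried, chosen before the data were examined, were DESeq2-style size factors, library size only (plain CPM), other filters and prior counts, the deposited RPKM values, DESeq2 1.42.0, a preset biological coefficient of variation of 0.4, a test against a 2-fold change, a fit on the 3 libraries of a comparison, and leaving out each QSC mouse. The preset coefficient of variation was used with edgeR's likelihood ratio test and the same spread for every gene. Plain CPM for edgeR's calls and for named genes, and TMM factors computed without the stress list, were added after seeing the data.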

Results

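The series compared the transcriptomes of induced myogenic progenitor cells (iMPCs), muscle progenitors made from mouse fibroblasts by direct reprogramming, with those of satellite cells, the stem cells of skeletal muscle. RNA-seq counts were given for quiescent satellite cells (QSC, n = 2 mice), activated satellite cells (ASC, n = 1), iMPCs sorted as positive or negative for a Pax7 reporter (n = 1 each) and mouse embryonic fibroblasts (MEFs, n = 1). Library totals ranged from 20859611 counts in ASC to 29279686 in QSC of mouse 1, and 18309 to 19545 genes had at least 1 count. Expression is given as CPM, counts scaled to library size and by TMM, with the QSC values of mouse 1 and mouse 3 in that order, and fold changes on the log2 scale. Pairs given as by mouse are the log2 difference, list median or fold against mouse 1 alone and mouse 3 alone. For genes, by-mouse log2 differences are of log2 CPM with a prior count of 2. The log2 estimates of genes printed beside them are edgeR's, so a pair need not average to them. Groups of 1 library have no replicate check, and intervals cover counting error only.

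The QSC libraries differed from all others in composition. The 25 genes of the immediate early and dissociation stress list took 6.0% and 7.44% of QSC counts, against 0.177% in ASC, 0.258% and 0.309% in Pax7-positive and Pax7-negative iMPCs and 0.294% in MEFs. TMM factors of the QSC libraries lay well below the others, and scaling by library size alone moved the median log2 difference of all genes against QSC from 0.01 to 0.63 for Pax7-positive iMPCs, from 0.21 to 0.89 for Pax7-negative iMPCs, from 0.08 to 0.64 for ASC and from 0.05 to 0.63 for MEFs; changes are given relative to the TMM scale. The QSC mice also differed from each other: proliferation genes were higher in mouse 1 by a median of 2.83, endothelial markers by 2.83 and erythroid markers by 6.0. Across 17116 genes, which are not independent replicates, Pearson correlations of log2 CPM among 15 pairs of libraries were highest between the iMPC fractions (0.944) and between the QSC mice (0.940), with Spearman values of 0.949 and 0.950. Pax7-positive iMPCs correlated at 0.899 with ASC, 0.882 with MEFs, 0.801 with QSC of mouse 1 and 0.759 with QSC of mouse 3 (Spearman 0.907, 0.892, 0.815 and 0.773).

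Pax7-positive iMPCs were compared with QSC to ask how closely the reprogrammed progenitors resembled the resident stem cell. In Pax7-positive iMPCs Pax7, the transcription factor that marks satellite cells (ENSMUSG00000028736), was at 37.8 CPM against 34.5 and 159.7 CPM in QSC. Myod1, the muscle determination factor (ENSMUSG00000009471), was at 719 against 1836 and 629.6 CPM. Neither difference passed the test, which called 8 of 50 simulated genes changed 4-fold, so this does not show likeness. The ASC library had Myod1 at 1029 CPM, between the QSC mice, so its level did not separate quiescent from activated cells. Most listed genes of cell division and of fetal growth rose and most stress and cAMP-responsive genes fell, while quiescence genes went both ways, 3 of 24 up and 9 down, Calcr and Cd34 among the latter. Myf5, an early myogenic factor (ENSMUSG00000000435), fell by 4.86 ± 0.82 (SE) to 3.57 CPM from 84.2 and 124 CPM. In all, 3524 of 17116 genes changed, 1931 up and 1593 down.

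**Figure D1:**
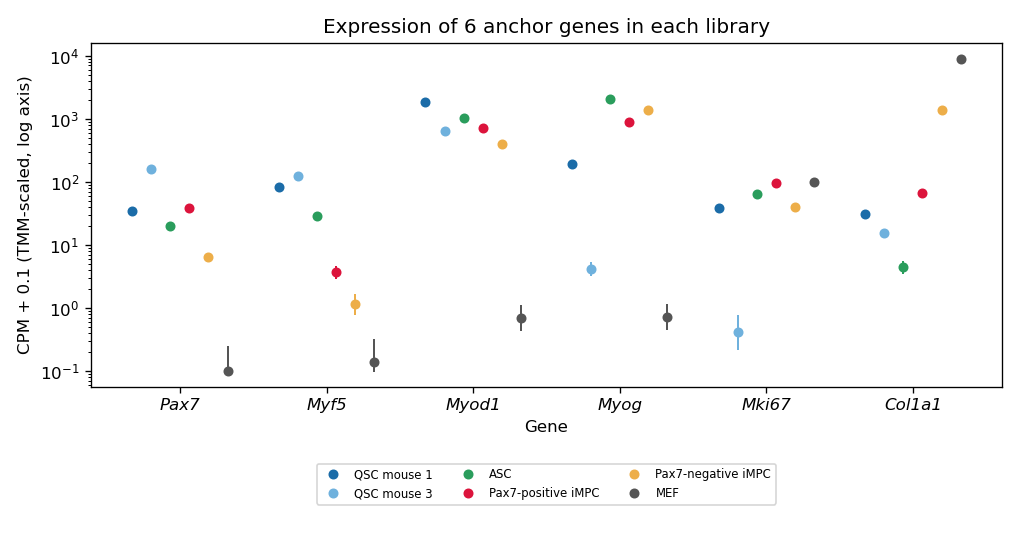
Expression of Pax7, Myf5, Myod1, Myog, Mki67 and Col1a1 in each of the 6 libraries, as CPM plus 0.1 on a logarithmic axis; points are libraries and bars are exact 95% counting intervals. Pax7 was at 37.8 CPM in Pax7-positive iMPCs, 6.25 CPM in the Pax7-negative fraction and 0 counts in MEFs, and Myf5 was highest in the QSC libraries (84.2 and 124 CPM).

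Of 20 satellite cell identity genes, 2 rose and 6 fell in Pax7-positive iMPCs (2 and 7 when adjusted over the list alone), with a median difference of -0.44 that turned to 0.23 under library size scaling and to 0.09 without mouse 3. Sdc3, a syndecan of the satellite cell surface, rose by 3.66 ± 0.61 to 333 CPM, whereas Pax3, the paralog of Pax7, had 2 counts and stood 599-fold lower than in QSC (counting interval 166 to 4951; by mouse 318 and 866; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000237). Of 24 quiescence genes, 3 rose and 9 fell (4 and 10 over the list alone; median -0.81, percentile 1.05 of random lists). The calcitonin receptor gene Calcr fell by 8.63 ± 1.12 (by mouse -7.38 and -8.82) from 55.9 and 151 CPM to 0.257 CPM, and Cd34, a surface marker of QSC, fell by 7.21 ± 0.90 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.18e-05 and 6.39e-05). Chrdl2, a chordin-like BMP antagonist, had 2 counts against 604 and 643 CPM, a 9703-fold difference (2686 to 80130).

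Myogenic commitment genes moved in both directions: of 20, 3 rose and 4 fell (4 and 4 over the list alone), with a median of 0.48 (percentile 80.7) that turned to -0.16 without mouse 3. Myog, the factor of terminal commitment (ENSMUSG00000026459), was at 892 CPM against 189 and 4.07 CPM, a difference of 3.21 ± 1.12 (by mouse 2.24 and 7.75) that missed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0513), and Chrng, the fetal acetylcholine receptor subunit, rose by 4.14 ± 0.93 (by mouse 3.21 and 7.19). Of 35 sarcomere genes 17 rose and 3 fell (19 and 4 over the list alone; median 2.20, percentile 100, by mouse 1.58 and 3.05). Actc1, cardiac actin of developing muscle, rose by 5.08 ± 1.16 to 1084 CPM (by mouse 4.11 and 9.27). Myh3, embryonic myosin, rose by 4.61 ± 0.74 to 47.7 CPM (by mouse 4.05 and 5.36). In QSC, 7 of 20 commitment and 8 of 35 sarcomere genes were at least 4-fold higher in mouse 1 than in mouse 3.

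Proliferation genes rose as a group: 24 of 28 passed the test upward and 0 downward (25 and 0 over the list alone; median 4.58, percentile 100, by mouse 2.82 and 6.04). Ccnb1, the mitotic cyclin B1, rose by 5.77 ± 1.01 to 338 CPM (by mouse 4.82 and 9.09) and Plk1, a mitotic kinase, by 6.41 ± 0.78 to 169 CPM (by mouse 5.67 and 7.72; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00084 and 5.82e-05). Mki67 (ENSMUSG00000031004) was at 94.7 CPM against 38.4 and 0.317 CPM and did not pass; 19 of the 28 genes were at least 4-fold higher in QSC of mouse 1, where endothelial and erythroid markers were also higher.

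Imprinted and fetal growth genes rose in 11 of 19 cases and fell in 2 (13 and 3 over the list alone; median 2.24, percentile 100). Igf2bp1, a fetal mRNA-binding protein, was at 89.5 CPM against 2 counts in QSC, 1928-fold higher (533 to 15930). Both counts were in mouse 1, against which it was 939-fold higher. The fetal chromatin protein Hmga2 rose by 7.06 ± 0.73 to 59.8 CPM (by mouse 6.33 and 7.62; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.86e-06 and 1.83e-05). Other genes with the largest increases were Nrk, a kinase, at 383 CPM against 0.429 and 0.0452 CPM, the sodium channel subunit Scn3b at 415 CPM, and the serotonin receptor Htr1b, which had 0 counts in QSC and was at least 679-fold higher (by mouse at least 331 and 349).

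Expanded iMPC cultures were kept with forskolin, RepSox and a GSK3 inhibitor, per the labels' protocols, which act on the cAMP, TGF-beta and Wnt pathways. Whether these drugs changed any list was not tested. MEFs, whose medium the labels do not give, stood against QSC at medians of -3.20 for cAMP, 0.93 for TGF-beta and 2.68 for Wnt response genes. For Pax7-negative iMPCs against QSC the medians were -1.62, -0.43 and 3.64. Of 20 TGF-beta response genes, 4 rose and 7 fell (4 and 9 over the list alone; median -1.72, percentile 0.01). Pmepa1, a feedback inhibitor induced by TGF-beta, fell by 7.96 ± 1.00 from 1733 and 1499.7 CPM to 6.47 CPM and Ctgf fell by 6.72 ± 0.91, whereas Mstn, which encodes the ligand myostatin, rose to 164 CPM from 1.29 and 0.0452 CPM. Of 17 Wnt response genes, 6 rose and 1 fell (6 and 1 over the list alone, median 0.97, percentile 93.3, by mouse 1.57 and 1.11). The list member Lgr5 rose by 5.90 ± 0.78 and Bmp4 fell by 9.02 ± 1.01 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.79e-05 and 2.79e-05). Among 15 cAMP response genes 0 rose and 9 fell (0 and 10 over the list alone; median -2.91, percentile 0), and Nr4a3, an orphan nuclear receptor that is also an immediate early gene, had 0 counts, against 58.2 and 213 CPM in QSC (by mouse at least 603-fold and 2205-fold lower). Of 25 immediate early and stress genes 0 rose and 23 fell (0 and 24 over the list alone; median -4.19, percentile 0), including the heat shock gene Hspa1a, from 22960 and 24292 CPM to 3.25 CPM, and Atf3, which fell by 11.02 ± 1.17.

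Of 15 Notch pathway genes, 4 rose and 1 fell (4 and 1 over the list alone; median 0.57, percentile 77.6); Lfng, a modifier of Notch, rose by 6.35 ± 0.86, and Numb, a Notch inhibitor, fell by 2.45 ± 0.71. Of 27 fibroblast and matrix genes 10 rose and 3 fell (10 and 4 over the list alone; median 0.48, percentile 86.2). Fibronectin (Fn1) rose by 4.53 ± 0.67 to 215 CPM, the proteoglycan Dcn fell by 4.40 ± 0.77, and collagen Col1a1 (ENSMUSG00000001506), at 66.5 against 31.2 and 15.6 CPM, did not pass. Of 34 Hox genes 2 rose and 5 fell (7 and 8 over the list alone; median -0.39, or -0.10 with zero-count genes at their bound, and 0.05 both under library size scaling and without mouse 3), with Hoxb9 up by 6.23 ± 1.25 (by mouse 4.92 and 7.14) and Hoxc10 down (-4.82 ± 1.12). Of 17 glycolysis genes 1 rose and 2 fell over all genes and 0 in either direction over the list alone (median 0.51, percentile 95.5), with 3 higher and 3 lower at an unadjusted p under 0.05 and 1 and 3 called by DESeq2. Of 3 measured pluripotency genes 0 were called by edgeR, adjusted or not, or by DESeq2 (median 0.83, -0.11 at the bound).

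Immune and erythroid markers had negative medians against QSC in ASC (-4.46 and -5.39), Pax7-negative iMPCs (-4.01 and -5.90) and MEFs (-3.46 and -5.39). Falls in these lists are thus not particular to Pax7-positive iMPCs, and whether other cells in the QSC samples carried them was not tested. In Pax7-positive iMPCs most endothelial, immune and erythroid markers fell, and those of other cell types went in no common direction. Of 11 endothelial markers 8 fell (10 over the list alone; median -5.19, -5.11 at the bound, by mouse -6.69 and -3.91), of 11 immune markers 6 fell and 1 rose (7 and 1 over the list alone; median -3.76), and all 5 erythroid markers fell (5 over the list alone; median -6.79, -7.62 at the bound, but by mouse -10.00 and -3.59). Lyz2, the lysozyme of macrophages, had 0 counts against 182 and 54.4 CPM (by mouse at least 1885-fold and 564-fold lower). The globin gene Hbb-bs had 0 counts against 424 and 8.82 CPM (by mouse at least 4388-fold and 91.4-fold lower). Of 5 adipocyte markers 2 fell (2 over the list alone; median -2.08, by mouse -3.02 and -1.25), of 9 Schwann markers 3 fell and 2 rose (4 and 2; median -1.57), and of 11 cartilage and bone markers 2 fell and 1 rose (3 and 1; median 0, -1.11 at the bound). Of 10 pericyte and smooth muscle markers, which include the muscle gene Des, 2 fell and 1 rose (3 and 2; median -0.20, but 0.47 under library size scaling), and of 4 epithelial markers 0 were called by edgeR, adjusted or not, or by DESeq2 (median 0.72, but -0.26 without mouse 3).

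These calls assume that the single iMPC library varies like the QSC pair. The rule of size gave 1674 genes higher and 1652 lower; under library size scaling the split moved to 1998 up and 531 down for edgeR and to 2871 higher and 1039 lower by size, and in the deposited RPKM values it was 3084 and 1422. Other settings turned it the other way. DESeq2 called 1769 up and 2029 down, edgeR 1482 up and 1532 down with a filter of 5 CPM and 3097 up and 3484 down with a preset coefficient of variation of 0.4. The rule of size gave 1601 higher and 1732 lower with DESeq2-style size factors and 2134 higher and 2419 lower with a minimum of 1 CPM.

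Activated satellite cells, which have left quiescence, gave the same comparison within the muscle lineage. Against QSC, genes of the contractile apparatus rose throughout and 13 of 24 quiescence genes fell. Pax7 was at 19.8 CPM and Myf5 at 28.5 CPM, both lower without passing the test (-2.29 ± 0.85 and -1.87 ± 0.68; Pax7 by mouse -0.80 and -3.01). Myod1 was at 1029 CPM (-0.26 ± 0.74; by mouse -0.84 and 0.71), and Myog rose by 4.41 ± 1.16 to 2055 CPM (by mouse 3.44 and 8.95; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.012). In all 3432 genes changed, 2021 up and 1411 down.

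All 35 sarcomere genes rose in ASC (35 over the list alone; median 7.92, by mouse 6.70 and 8.96). Of 20 commitment genes 14 rose and 0 fell (14 and 0 over the list alone; median 3.47, by mouse 2.79 and 3.96). Embryonic myosin Myh3 reached 4413 CPM, an increase of 11.14 ± 0.92 (by mouse 10.58 and 11.89), and slow myosin Myh7 463 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.07e-07 and 4.13e-07); Tmem8c, the fusion protein myomaker, rose by 6.21 ± 1.29 to 1120 CPM (by mouse 5.22 and 11.85). Of 24 quiescence genes 0 rose and 13 fell (0 and 15 over the list alone; median -3.15), and Calcr had 0 counts, against 55.9 and 151 CPM in QSC (by mouse at least 432-fold and 1171-fold lower). Satellite identity genes rose in 3 of 20 cases and fell in 7 (3 and 9 over the list alone; median -0.58, 0.00 under library size scaling): Msc, the repressor musculin, fell by 10.22 to 0.215 CPM (by mouse -10.42 and -8.72) and Sdc3 rose by 4.12 ± 0.62. Proliferation genes rose in 14 of 28 cases (21 over the list alone; median 3.49, by mouse 1.79 and 4.77), with Plk1 up by 5.31 ± 0.75 (by mouse 4.57 and 6.62). Of 11 endothelial markers 8 fell (11 over the list alone; median -5.17, by mouse -6.37 and -3.97), of 11 immune markers 5 fell and 1 rose (7 and 1; median -4.46, -4.12 at the bound), and all 5 erythroid markers fell (5; median -5.39, by mouse -8.59 and -2.18). Of 4 epithelial markers 3 rose (3; median 4.04).

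Of the fibroblast list 6 of 27 genes fell and 3 rose (8 and 3 over the list alone; median -1.14); Dcn fell by 7.90 ± 0.94, Fn1 rose by 5.44 ± 0.69 and Col1a1 was at 4.31 CPM. Stress genes fell in 23 of 25 cases (23 over the list alone; median -4.81) and cAMP response genes in 9 of 15 (10; median -3.36, by mouse -2.61 and -3.67). Hes6, a promoter of myogenic differentiation, rose by 5.77 ± 0.64 to 1431 CPM, and Erbb3, a neuregulin receptor listed here among Schwann markers, by 7.05 ± 0.72. The rule of size gave 1903 genes higher and 1511 lower. The direction split depended on scaling and tool: library size scaling gave 1868 up and 501 down in edgeR and 2909 higher and 953 lower by size, RPKM values 3166 and 1324, and DESeq2 1762 up and 1951 down.

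Pax7-negative iMPCs were compared with QSC as the reporter-negative part of the cultures. They combined muscle and matrix genes: Myog rose by 3.82 ± 1.14 to 1358 CPM (by mouse 2.85 and 8.36) and Col1a1 by 5.88 ± 0.80 to 1377 CPM, while Pax7 fell by 3.96 ± 0.94 to 6.25 CPM (by mouse -2.45 and -4.66) and Myf5 fell by 6.63 ± 0.91 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0263, 9.43e-05, 0.00709 and 9.69e-05). Myod1 was at 404 CPM and Mki67 at 40.1 CPM, and neither passed. In all 3189 genes changed, 2065 up and 1124 down.

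Of 35 sarcomere genes 30 rose and 0 fell (31 and 0 over the list alone; median 5.05, by mouse 3.80 and 5.91), with Myh3 up by 8.33 ± 0.84 to 629 CPM (by mouse 7.76 and 9.08), and of 20 commitment genes 7 rose and 2 fell (8 and 3; median 0.84). Matrix and fibroblast genes rose in 16 of 27 cases and fell in 0 (19 and 1 over the list alone; median 2.55); the mesenchymal factor Twist2 rose by 9.16 ± 0.96 and the platelet-derived growth factor receptor Pdgfra by 7.09 ± 0.71 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1e-05 and 7.72e-06). Wnt response genes rose in 10 of 17 cases and fell in 2 (10 and 2; median 3.64), including Sfrp2 and Dkk2. Crabp1, a retinoic acid binding protein, had the largest increase, 11.15 ± 0.94 to 653 CPM (by mouse 10.08 and 12.37), and Krt19, a keratin, rose by 7.46 ± 0.88 to 33.4 CPM (by mouse 8.06 and 6.41). It is 1 of 4 epithelial markers, of which 2 rose (3 over the list alone; median 5.17, by mouse 3.41 and 6.36).

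Satellite identity genes fell in 8 of 20 cases and rose in 1 (10 and 1 over the list alone; median -1.72), quiescence genes in 8 of 24 with 3 rising (8 and 3; median -1.16), stress genes in 21 of 25 (22; median -3.85). Proliferation genes rose in 13 of 28 cases (17 over the list alone; median 3.36, by mouse 1.63 and 4.80), and glycolysis genes in 6 of 17 with 0 falling (7 and 1; median 1.31), led by the phosphofructokinase Pfkl, up by 3.63 ± 0.60. Of 11 endothelial markers 1 fell (0 over the list alone), with a median of -1.18 that turned to 0.60 without mouse 1 and was -2.81 without mouse 3. Of 11 immune markers 5 fell and 1 rose (6 and 1; median -4.01), and of 5 erythroid markers 4 fell (5; median -5.90, by mouse -9.10 and -2.69). The Notch median of -0.55 and the TGF-beta median of -0.43 turned to 0.16 and 0.28 under library size scaling. The Hox median of 0.49 turned to -0.03 without mouse 1 and was 1.37 without mouse 3. By the rule of size 1889 genes were higher and 1323 lower; library size scaling gave 2141 up and 329 down in edgeR and 3207 and 751 by size, RPKM values 3546 and 1028, and DESeq2 1719 and 1653.

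MEFs, the fibroblast reference, had little or none of the myogenic factors of QSC. Pax7 had 0 counts, against 34.5 and 159.7 CPM in QSC (by mouse at least 308-fold and 1425-fold lower), and Myf5 had 1 count. Myod1 fell to 0.598 CPM (SE of the log2 change 1.29, by mouse -11.41 and -9.86) and Myog fell by 7.24 ± 1.75, from 189 and 4.07 CPM to 0.635 CPM (by mouse -8.05 and -2.54, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.44e-05 and 0.00761). As a difference of mean log2 CPM, Myog stood at -5.29. Col1a1 rose by 8.57 ± 0.89 to 8924 CPM and Fn1 by 8.33 ± 0.77 to 3004 CPM. In all 3312 genes changed, 1938 up and 1374 down.

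Fibroblast and matrix genes rose in 22 of 27 cases and fell in 1 (22 and 1 over the list alone; median 3.65). Satellite identity genes fell in 14 of 20 cases (15 over the list alone; median -3.74), quiescence genes in 15 of 24 (18; median -2.92), commitment genes in 12 of 20 (13; median -2.99, -3.37 at the bound, by mouse -4.86 and -2.02) and sarcomere genes in 18 of 35 (19; median -2.29, by mouse -3.16 and -1.58), with 1 gene rising over all genes in each list but quiescence, which had 0. The receptor tyrosine kinase Fgfr4 fell by 10.37 ± 1.07 and Musk, the agrin receptor component, had 2 counts. Proliferation genes rose in 16 of 28 cases (23 over the list alone; median 3.45, by mouse 2.12 and 4.73) and stress genes fell in 22 of 25 (22; median -3.90). Hox genes rose in 11 of 34 cases and fell in 0 (11 and 0; median 1.58); Hoxd13, a limb patterning gene, had 0 counts in QSC and was at least 428-fold higher (by mouse at least 208 and 220). Cartilage and bone markers rose in 6 of 11 cases and fell in 2 (6 and 4; median 3.95), with the cartilage collagen Col2a1 at 277 CPM, and smooth muscle actin Acta2 rose by 3.31 ± 0.69 to 4039 CPM. Endothelial markers fell in 5 of 11 cases (6; median -3.90, by mouse -4.85 and -2.96), immune markers in 2 of 11 (6; median -3.46) and erythroid markers in 4 of 5 (5; median -5.39, by mouse -8.18 and -2.61), while epithelial markers rose in 2 of 4 (2; median 3.12, 3.30 at the bound, by mouse 1.36 and 4.88). By the rule of size 1847 genes were higher and 1495 lower; library size scaling gave 1836 up and 461 down in edgeR and 2964 and 922 by size, RPKM values 3226 and 1251, and DESeq2 1767 and 1934.

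Each of the other cell types was set against these ends, and a gene beyond an end counts as nearer to it. Of the 1495 genes higher in QSC than in MEFs by the rule of size, 298 (19.9%) were nearer to QSC in Pax7-positive iMPCs, 363 (24.3%) in Pax7-negative iMPCs and 311 (20.8%) in ASC. Within 2-fold of MEFs were 745 (49.8%), 793 (53.0%) and 804 (53.8%) in the same order. Of the 1847 genes lower in QSC, 595 (32.2%) were nearer to QSC in Pax7-positive iMPCs, 302 (16.4%) in the negative fraction and 459 (24.9%) in ASC. With ASC as the muscle end, Pax7-positive iMPCs lay nearer to ASC for 348 (43.2%) of the 806 genes higher in ASC and for 491 (70.4%) of the 697 lower. For Pax7-negative iMPCs these were 483 (59.9%) and 254 (36.4%), and for QSC 275 (34.1%) and 430 (61.7%). In Pax7-positive iMPCs, 98 genes higher and 210 lower in QSC lay beyond the QSC level. Beyond the ASC level lay 88 genes higher and 224 lower in ASC. The QSC ends include the stress genes and differ between the mice. The ASC library expressed terminal differentiation genes, such as Myh1 at 3632 CPM and Mb at 490.5 CPM. Nearness to it is therefore not nearness to undifferentiated activated cells.

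Pax7-positive iMPCs were set against MEFs to see how far the reprogrammed cells differed from a fibroblast. They carried a myogenic program that MEFs lacked: Pax7 was at 37.8 CPM against 0 counts, at least 338-fold higher, Myod1 was 1202-fold higher (counting interval 740 to 2103) and Myog 1404-fold higher (877 to 2411). Collagen Col1a1 was 134-fold lower (129 to 140.2), at 66.5 against 8924 CPM. Mki67, at 94.7 and 98.1 CPM, did not differ beyond counting error (ratio 0.965, 0.915 to 1.02). By the rule of size 554 genes were higher and 971 lower, with no replicate behind either group and no p-value. The labels do not say whether this MEF library is the starting culture of the iMPCs. Differences of origin and changes through reprogramming therefore cannot be told apart here or for the Pax7-negative fraction.

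Satellite identity genes were higher as a list (median 3.01, percentile 100), with 11 of 20 at least 4-fold higher and 0 lower. Cdh15, the adhesion molecule M-cadherin, was at 962 CPM (1119-fold, 746 to 1766) and the growth factor receptor Fgfr4 at 379.5 CPM (1269-fold, 644 to 2941). Of 24 quiescence genes 8 were at least 4-fold higher and 1 lower (median 0.80); the Notch target Heyl was 552-fold higher and the cell cycle inhibitor Cdkn1c, an imprinted gene, reached 4143 CPM against 42.0. Commitment genes (median 4.79; 10 higher and 1 lower of 20) and sarcomere genes (median 4.18; 22 of 35 higher) followed, with Chrng 1480-fold higher (409 to 12230) and Actc1 527-fold higher (405 to 700.1). Mstn, with 1 count in MEFs, was 4391-fold higher (788 to 173500), and Pitx3, a homeobox gene of muscle, had 0 MEF counts and was at least 1390-fold higher.

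Fibroblast and matrix genes were lower in 26 of 27 cases, 17 of them at least 4-fold (median -2.80), with 1 at least 4-fold higher. Periostin (Postn) was 69.9-fold lower (60.5 to 81.1) and fibulin 2 (Fbln2) 59.1-fold lower. TGF-beta response genes were lower (median -2.23), with Ctgf 265-fold lower, and so were Wnt response genes (median -2.23), although Lgr5 was 13.6-fold higher. The Hox list was lower (median -1.53, percentile 0.01), with distal Hoxd11 at 0 counts, at least 170.4-fold lower. Cartilage and bone markers were lower (median -3.66). Notch genes were higher by a median of 1.41 (0.20 with zero-count genes at their bound), led by the ligand Dll1, 393-fold higher (153 to 1445). Imprinted genes were mixed (median 0.30, 5 higher and 1 lower of 19), with Mest at 3427 against 183 CPM. The medians of proliferation, glycolysis and stress genes were 0.72, 0.06 and -0.44.

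The Pax7-positive and Pax7-negative fractions of the iMPC cultures were compared to see what separates cells on either side of the reporter sort. Pax7 itself was 6.06-fold higher in the positive fraction (5.18 to 7.11), at 37.8 against 6.25 CPM. The fractions were unequal in direction: 23 genes were at least 4-fold higher in the positive fraction and 736 lower. Sarcomere, fibroblast and several marker genes were higher in the negative fraction, and proliferation genes in the positive one.

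Of 35 sarcomere genes 34 were lower in Pax7-positive cells, 25 at least 4-fold (median -3.05), with Mybph 20.1-fold lower (18.2 to 22.2), while commitment genes were lower (median -0.47), Myog by 1.52-fold (1.499 to 1.545) and Mef2c, a muscle transcription factor, by 10.9-fold. Myod1 was 1.78-fold higher (1.74 to 1.82). All 28 proliferation genes were higher, 2 at least 4-fold (median 1.22): the G1 cyclin Ccne1 was 4.35-fold and the ribonucleotide reductase subunit Rrm2 4.19-fold higher. Satellite identity genes were higher by a median of 0.87 (percentile 100), with the chemokine receptor Cxcr4 4.58-fold and Met 4.03-fold higher, and the Notch-linked genes Lfng and Nrarp were 5.64-fold and 4.06-fold higher. Dmrt2, a transcription factor of the dermomyotome, had the largest increase, 16.3-fold (12.5 to 21.6). The quiescence median was near 0 (0.03, and -0.01 under library size scaling), yet Cd34 was 34.9-fold lower (25.8 to 48.2).

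Genes of the fibroblast list were lower in Pax7-positive cells in 25 of 27 cases, 13 at least 4-fold (median -1.91). The proteoglycan Lum was 50.4-fold lower (43.0 to 59.5), Pdgfra 47.1-fold and Col1a1 20.7-fold (19.8 to 21.7). Complement C3, with 1 count, was 634-fold lower (113 to 25080), the secreted protein Spon2 83.3-fold lower, and Mmp3, a matrix protease, 69.3-fold lower. Endothelial markers were lower in 11 of 11 cases (median -2.90), and pericyte and smooth muscle (median -1.93), adipocyte (-2.77) and epithelial markers (-5.03) were lower too, with Krt19 57.6-fold lower. cAMP response genes were lower in 14 of 15 cases (median -1.35), as were TGF-beta (median -1.04) and Wnt response genes (-1.67) and 16 of 17 glycolysis genes (-0.70), the lactate exporter Slc16a3 by 5.81-fold. These ratios compare 1 sorted library with another.

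Against the ASC library, the endogenous activated cells of the series, Pax7-positive iMPCs had less of the contractile program. That library expressed terminal differentiation genes, with Myh1 at 3632 CPM and Mb at 490.5 CPM. The difference therefore cannot be read as one from undifferentiated activated cells. Pax7 was 1.91-fold higher (1.71 to 2.13), Myod1 1.43-fold lower (1.41 to 1.46), Myog 2.303-fold lower (2.27 to 2.34) and Myf5 7.99-fold lower (6.52 to 9.85). All 35 sarcomere genes were lower, 33 at least 4-fold (median -6.19), with Myh1 326-fold lower (294 to 364), and all 20 commitment genes were lower, 13 at least 4-fold (median -2.99), with Klhl41 55.2-fold and Mef2c 41.4-fold lower. Past the rule of size were 392 higher and 875 lower genes.

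Satellite identity genes lay near 0 as a list (median -0.04, but 0.00 with DESeq2-style size factors and 0.04 under library size scaling); Msc was 149.7-fold higher and Fgfr4 8.45-fold higher, whereas Pax3 was 95.7-fold lower with 2 counts (26.0 to 798). Quiescence genes were higher by a median of 1.38 (1.06 at the bound), 9 of 24 at least 4-fold, including Cdkn1c, 32.1-fold higher. Fibroblast and matrix genes were higher by a median of 1.45, with Pdgfrb 30.8-fold (24.6 to 39.0) and Col1a1 15.4-fold higher. Imprinted genes (median 0.87, 0.80 at the bound) included Grb10, 38.4-fold higher, and the growth regulator Gpc3 was 311-fold higher (231 to 430.3). Proliferation genes were higher by a median of 1.08, with Ccne1 12.5-fold higher. TGF-beta response genes were lower (median -0.91), with Pmepa1 29.96-fold and the feedback regulator Skil 16.2-fold lower. The Hox list went both ways (median -0.77), Hoxa11 118-fold lower and Hoxb9 127-fold higher (34.9 to 1053). Xist was 907-fold higher with 1 count in ASC, and the Y-linked Ddx3y had 0 counts in Pax7-positive iMPCs, at least 883-fold lower. The libraries differ here as a female and a male source do, so this comparison includes any difference between the sexes.

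**Figure D2:**
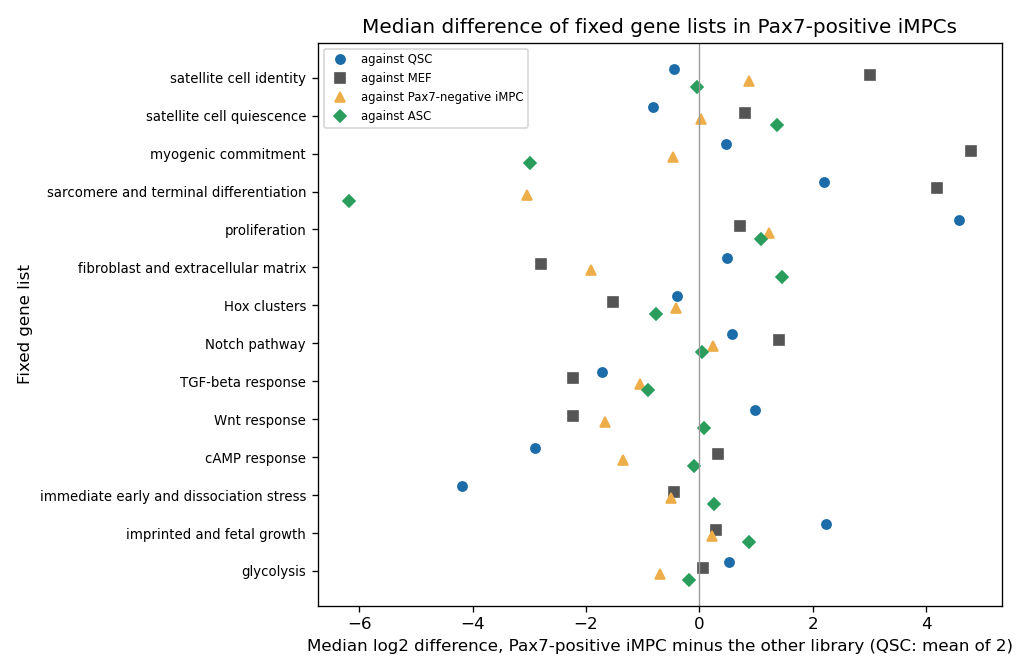
Median log2 difference of 14 gene lists between Pax7-positive iMPCs and QSC, MEFs, Pax7-negative iMPCs and ASC, with each list on 1 line and each comparison as a point; values right of 0 are higher in Pax7-positive iMPCs. Sarcomere genes lay at 2.20, 4.18, -3.05 and -6.19 in that order, and the medians of identity (-0.44), commitment (0.48) and Hox genes (-0.39) against QSC, identity against ASC (-0.04) and quiescence against Pax7-negative cells (0.03) change sign under another scaling or without mouse 3.

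Pax7-negative iMPCs were also set against MEFs. Muscle genes were higher than in fibroblasts: sarcomere genes by a median of 7.05 (31 of 35 at least 4-fold), commitment genes by 6.01 (12 of 20) and satellite identity genes by 2.53 (9 higher and 1 lower of 20). Myog was 2138-fold higher (1335 to 3670), Myod1 676-fold (416 to 1182), and Pax7, at 6.25 CPM, at least 55.7-fold higher. Col1a1 was 6.48-fold lower (6.41 to 6.55) at 1377 CPM, and Mki67 2.45-fold lower (2.29 to 2.62). Past the rule of size were 810 higher and 407 lower genes.

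Fibroblast and matrix genes were lower (median -0.76), 8 of 27 at least 4-fold lower and 2 higher, with the crosslinking enzyme Lox 11.8-fold lower and Fap, a surface protease, 12.6-fold higher (9.81 to 16.3). Cdkn1c was 89.0-fold higher (83.9 to 94.5). cAMP response genes were higher by a median of 1.39, 5 of 15 at least 4-fold, with the ligand Areg 16.7-fold and the phosphodiesterase Pde4b 10.5-fold higher. Glycolysis genes were higher in 16 of 17 cases (median 0.76), Slc16a3 by 9.37-fold. TGF-beta response (median -0.74) and Hox genes (-1.26) were lower, with Ctgf 41.4-fold and Hoxd13 67.8-fold lower. Proliferation genes were lower (median -0.55), 0 of 28 by 4-fold, and the stress list was level (-0.02, 0.06 under library size scaling). Pericyte and smooth muscle markers went both ways, with 3 of 10 at least 4-fold higher and 4 lower (median -0.85): the proteoglycan Cspg4 was 144-fold lower (102 to 209) and Acta2 5.38-fold lower, whereas the potassium channel subunits Kcnj8 and Abcc9 were 92.3-fold (64.1 to 138) and 63.1-fold (44.3 to 93.1) higher.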

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

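No test was run in this part, so none was chosen after the result was seen: each iMPC fraction and the MEFs are 1 library, and the difference between the fractions was not tested. The 5 genes here differed from MEFs in opposite directions in the 2 iMPC fractions, at least 4-fold each way, which singled them out. They came from 785 genes that passed the rule of size in both comparisons. Crabp1, a retinoic acid binding protein, was lower than in MEFs in Pax7-positive iMPCs (-2.34) and higher in Pax7-negative iMPCs (3.22), at 13.8, 653 and 70.1 CPM in the positive fraction, the negative fraction and MEFs. Ednrb, the endothelin receptor B of neural crest cells, differed by -3.12 and 2.61 (1.32, 74.1 and 12.1 CPM). Frzb, a secreted Wnt antagonist, differed by -2.84 and 2.95 (1.13, 66.3 and 8.52 CPM). Gdf10, a BMP family ligand, differed by -3.08 and 2.78 (0.740, 47.4 and 6.84 CPM). Pla2g7, a secreted phospholipase, differed by -2.01 and 2.14 (2.48, 45.5 and 10.2 CPM).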

How the results depend on the processing

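Plain CPM for edgeR's calls and for named genes, and TMM without the stress list were tests chosen only after the data were seen; all others were planned. No paired analysis was possible because only QSC has more than 1 library and no other group shares 2 mouse numbers. Leaving out a QSC mouse leaves no residual degrees of freedom, so those settings gave values and no calls. Against QSC, more genes went up than down, but this split turned under DESeq2 for Pax7-positive iMPCs (1769 up and 2029 down), ASC (1762 and 1951) and MEFs (1767 and 1934). For Pax7-positive iMPCs it also turned with a filter of 5 CPM (1482 and 1532), with the preset coefficient of variation (3097 and 3484) and, by the rule of size, with DESeq2-style size factors (1601 and 1732) and a minimum of 1 CPM (2134 and 2419); the cause was not tested. Some list medians changed sign, as given below. The counts of genes changed against QSC stayed within 1.5 times under DESeq2-style size factors, other filters, plain CPM, TMM without the stress list (3514, 3195, 3429 and 3315), DESeq2 and fits on 3 libraries. They did not with a preset coefficient of variation of 0.4. That gave 6581 genes for Pax7-positive iMPCs, 6334 for Pax7-negative iMPCs, 6534 for ASC and 6493 for MEFs. Nor did they in the test against a 2-fold change, which gave 2320, 2070, 2281 and 2158. The preset setting used a smaller spread, the same for every gene, and a likelihood ratio test in place of the quasi-likelihood F test. The 2-fold test has a stricter null. The part that each of these played was not tested. With a minimum of 1 CPM the rule of size took in more genes, 1283 between the iMPC fractions, 1920 for Pax7-positive iMPCs against ASC and 1915 for Pax7-negative iMPCs against MEFs, as its lower limit admits more genes. The share of genes higher in QSC that lay nearer to QSC in Pax7-positive iMPCs was 24.0% under plain CPM and 16.7% to 20.7% without either mouse, and for genes lower in QSC 24.7% and 29.8% to 32.9%; the cause was not tested. The Pearson correlation of QSC of mouse 3 with Pax7-negative iMPCs was 0.710 with a prior count of 0.5.

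Of 547 named differences of at least 4-fold, 2 dropped below it with DESeq2-style size factors, 18 under plain CPM and 0 with a prior count of 0.5; of 298 against QSC, 7 dropped without mouse 1 and 12 without mouse 3, and 0 changed sign. With n = 2, a change on leaving out 1 mouse cannot exceed the SD, so only the side of the 4-fold limit is informative. Of 184 list medians 3 changed sign with DESeq2-style size factors, 11 under plain CPM and 0 with a prior count of 0.5; of 92 against QSC, 3 changed sign without mouse 1 and 5 without mouse 3. Those not given in the report were the Notch and TGF-beta medians of ASC against QSC (-0.58 and -0.53, and 0.01 and 0.06 under plain CPM), Schwann markers between the fractions (-0.02, with DESeq2-style size factors 0.04) and adipocyte markers in Pax7-negative iMPCs against QSC (0.06, with DESeq2-style size factors -0.06, without mouse 1 or 3 -0.24 and -0.25). Depth limits genes at 3 counts or fewer, whose ratios span wide intervals.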

Other observations

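All tests of explanations in this part were chosen only after the results were seen. Some genes outside the lists, chosen after their values were seen, separated the libraries. Pax7-negative iMPCs had more Bnip3 (290.2 against 48.0 CPM in Pax7-positive iMPCs), Vegfa (234 against 51.5) and Car9 (29.9 against 7.53); no list of related genes was tested. Ndrg1 was at 1434 and 1051 CPM in QSC and 9.04 CPM in Pax7-positive iMPCs. Reads counted to Lars2, a mitochondrial tRNA ligase, were at 81.1 and 271 CPM in QSC and at 6090 to 8203 CPM in the other libraries. Whether these reads came from its mRNA was not tested, so they are not given as a change in its expression. The Y-linked Ddx3y was at 455 CPM in QSC of mouse 1 and 85.2 CPM in ASC and under 1 CPM elsewhere, whereas Xist was at 530.1 CPM in QSC of mouse 3, 39.1 and 24.7 CPM in the Pax7-positive and Pax7-negative iMPCs and 41.9 CPM in MEFs.

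The 4 imprinted and quiescence genes given here, also chosen after their values were seen, stood higher in both iMPC fractions than in the other 4 libraries and do not stand for their lists: Hmga2, for example, was at 59.8 and 125 CPM in Pax7-positive and Pax7-negative iMPCs and 356 CPM in MEFs. The growth inhibitor Cdkn1c was at 4143 and 3735 CPM in Pax7-positive and Pax7-negative iMPCs, 691 and 71.0 CPM in QSC, 129 CPM in ASC and 42.0 CPM in MEFs. Itm2a was at 4103 and 1829 CPM in the same fractions, 1425 and 263 CPM in QSC, 618 CPM in ASC and 141 CPM in MEFs. Igf2 was at 1779.8 and 1833 CPM, with 112 and 98.1 CPM in QSC, 694 CPM in ASC and 540 CPM in MEFs, and H19 at 1431 and 1233 CPM, with 17.3 and 28.2 CPM in QSC, 1090 CPM in ASC and 332 CPM in MEFs.

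Proliferation genes were higher in QSC of mouse 1 than of mouse 3 by a median of 2.83, and 7 of 20 commitment genes by at least 4-fold. Cells like the sequenced ASC library are argued against as the source of the proliferation difference. A share of 0.189 would be needed, yet sarcomere genes rose by a median of 0.0138 of what that share would bring, with 30 of 35 under 0.1. Sarcomere genes were still higher in mouse 1 in 32 of 35 cases (median 1.37). The test cannot speak to activated cells with little sarcomere expression. Endothelial or blood cells in mouse 1 were considered as another source. Endothelial markers were higher by 2.83 too, but the share of such cells was not estimated. The prediction also required that no commitment gene be 4-fold higher, and 7 of 20 were. The test therefore cannot tell whether such cells account for the proliferation difference. This stays open, as do the age, sex and state of the mice, which were not tested. The difference in the commitment genes, led by Tmem8c (6.63), Myog (5.51) and Gm7325 (4.83), stays open too, and no explanation of it was tested.

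Immediate early and heat shock genes were far higher in QSC than in any other library. The scaling of the libraries is argued against as the cause, since the median difference of the list in Pax7-positive iMPCs against QSC was still -3.52 under library size alone. Handling during isolation and the state of the cells in muscle cannot be told apart: 23 of 25 genes were higher in each QSC library than in every other library, and both QSC libraries come from 1 kind of source while no other group does. A candidate explanation, as a hypothesis only, is that dissociation induced them; a QSC library from another source that lacked the rise would bear on it, and the series has none.

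Fibroblast and matrix genes were higher in Pax7-negative than in Pax7-positive iMPCs. MEFs like the sequenced library, left in the negative fraction, could account for part of them. From Pax7-positive to Pax7-negative iMPCs, 26 list genes rose by a median of 0.317 of their MEF level (10th to 90th percentile 0.0630 to 2.03). Another 53 genes, chosen as abundant in MEFs and low in Pax7-positive iMPCs, rose by a median of 0.0863 (0.0141 to 0.315). A mixture would bring similar shares, and the ratio of these medians was 0.272. The shares of single genes spread widely and overlap between the sets, which leaves this open. Such MEFs are argued against as the only source of the rise in 4 genes. These were picked for standing at least 2-fold above both MEFs and Pax7-positive iMPCs, and no mixture of these libraries could reach such levels. That outcome was fixed by the pick and does not speak to whether MEFs were present. The genes were Pdgfrb (388 CPM against 173 and 103), Dcn (417 against 40.6 and 12.3), Lum (249.7 against 101 and 4.95) and Twist2 (68.6 against 18.1 and 1.93). Fibroblasts altered in the cultures need not match the MEF library, so the test cannot speak to them. What raised these 4 genes was not tested; tail-tip fibroblasts, which the labels also name as a starting cell, were not analysed here.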
